A study of Drosophila melanogaster with 8 samples.

How the data were processed

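The series covers ovaries of Drosophila melanogaster females aged 0 to 4 days in 8 samples: 4 RNA-seq libraries, with 2 controls (progeny of tj-Gal4 and a VDRC control line) and 2 HP1a knockdowns (progeny of tj-Gal4 and an HP1a RNAi line), and 4 DamID samples, with 2 Dam-HP1 and 2 Dam only. Per the labels, poly(A)+ RNA came from about 100 ovaries per library and was sequenced as single-end reads of 50 nt, with 19 to 39 M reads. The DamID samples came from 160 to 200 ovaries each, with 16 PCR cycles and about 30 M reads of 100 nt. Per the submitters' processing notes, Salmon, HISAT2, DESeq2 and HTSeq were used for RNA-seq and Bowtie2 and HTSeq for DamID, with the builds dm3 and BDGP5; neither versions nor roles are stated.

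The deposited gene tables hold expected counts (estimated reads per gene from Salmon, not normalized) for 13776 genes, of which 13484 could be given a symbol. The deposited TPM values sum to 1000000 in each library. The deposited lengths and effective lengths of genes, in nt, entered an alternative and a test. The deposited domain list gives start and end positions of HP1 domains from a hidden Markov model, in steps of 500 bp, with other columns absent; how the 2 replicates were pooled and how the model was set are not stated. Positions are printed counted from 1, and dm3 is taken from the processing notes. The gene table used as a reference is of Release 6 and served only for the chromosome arm and the order of genes.

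Expected counts rounded to whole numbers were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (8798 kept, 4978 not), libraries were scaled by TMM (factors 0.92, 0.92, 1.11 and 1.06 for control 1, control 2, knockdown 1 and knockdown 2), and the groups were compared by the quasi-likelihood F test with no block. The p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The biological coefficient of variation was 0.245 with 2 residual degrees of freedom. The labels do not say that the libraries of a group come from separate crosses, so that p-values measure only the spread between samples. Log2 fold changes are knockdown minus control. Each SE is the absolute log2 fold change divided by the square root of its F statistic. It was not estimated separately from the spread between libraries. Counting intervals at 95% and floors of 3 counts over a group cover counting error only. CPM values use the scaled library sizes.

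The gene lists comprised chromosome 4 genes, pericentric heterochromatin genes, piRNA pathway genes, heterochromatin factors, follicle cell genes, eggshell genes, yolk proteins and uptake, germline genes, testis-biased genes, apoptosis and JNK genes, heat shock genes, detoxification genes, immune genes, DNA replication genes, mitosis genes, ecdysone genes, muscle genes, hemocyte and basement membrane genes, fat body genes, gut genes, secretory genes of the female tract, neural genes, ribosomal protein genes and mitochondrial transcripts. Lists were matched by symbol and tested with camera at a correlation of 0.01 when at least 5 members were tested (23 lists), adjusted over the lists; camera with an estimated correlation and fry from limma 3.58.1 were run beside it. Of the 23 lists, 8 passed with the preset correlation, 0 with the estimated correlation and 2 with fry (chromosome 4 genes, and yolk proteins and uptake). With the estimated correlation the smallest adjusted p was 0.700, shared by many lists. Their unadjusted camera p ran from 0.0806 (chromosome 4 genes) to 0.426 (DNA replication genes). The correlation was estimated with 2 residual degrees of freedom, so it is itself uncertain. Ribosomal protein genes, with 82 of 83 negative, did not pass under it. Members that vary together between libraries can share a sign without a group effect, so this does not show that the estimate fails. The list calls therefore rest on the preset correlation of 0.01, and their adjusted p-values are too small where members vary together more than that. Fry asks whether a list moves one way on balance and does not compare it with other genes. Arms with at least 20 tested genes were tested likewise. Adjacent called genes were counted over 8581 genes placed on an arm, against 10000 reassignments of the calls.

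The design, the lists, the alternatives and the rule for named genes were chosen before the data were examined. By that rule the text names the gene of HP1a, the 12 largest rises and the 12 largest falls among genes past the threshold with a mean of at least 50 counts and no overlap between groups, up to 4 members of each list with the smallest adjusted p, and the 3 longest domains. Other list members named (among them tj, cas, Cad99C, Fas3, dome, ttk, Cp15, fs(1)Yb, piwi, armi, Hml, NimC1, the laminin genes and EcR) and the runs of neighbours were chosen after their values were seen.

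The alternatives were other scales (median-ratio size factors, upper quartile, library size alone, TMM without eggshell, yolk, mitochondrial and the 20 most counted genes), other tests (DESeq2 1.42.0, limma-voom, limma-trend on TPM with pseudocounts of 1 and 0.1), a length offset, other filters (none, or at least 10 counts in every library), a block for the replicate number, each library left out, an adjusted p of 0.01, an absolute log2 fold change of at least 1, and for domains a minimum of 1000 bp or merging of those closer than 1000 bp. Scaling to the germline list, summing near-identical copies and the alternatives for arms and neighbours were added after the data were seen.

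The test was tested on simulated data with 2 libraries per group and 8624 genes. In 1 draw it called 6% of genes changed 1.5-fold, 26% of those changed 2-fold, 92% at 4-fold and 100% at 8-fold, and 8.03% of its calls were unchanged genes. Over 10 further draws these shares were 0% to 8%, 24% to 52%, 82% to 94% and 94% to 100%, with 5.15% to 10.6% of calls unchanged. The simulation changed 50 genes at each fold and a further list of 30 genes 2-fold. That is far fewer than the 2455 called in the data, so these shares need not hold there. Domains were summarised in Python 3.11.15 with pandas 2.3.3, and figures drawn with matplotlib 3.10.9. No test between Dam-HP1 and Dam only was made, since values per DamID sample were not used here. The overlap of domains with genes was left out because no gene coordinates in dm3 were at hand.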

Results

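RNA-seq of ovaries from females aged 0 to 4 days covered 2 control libraries and 2 libraries labelled HP1a knockdown, in which tj-Gal4 drives the RNA interference in somatic cells. RNA came from about 100 ovaries per library, so that germline RNA was measured together with somatic RNA. The groups also differ in the line crossed to tj-Gal4, so effects of the knockdown and of the line cannot be told apart. The deposited counts summed to 20633184 and 21862077 in control 1 and control 2, and to 18671653 and 38330979 in knockdown 1 and knockdown 2. Of 13776 genes, 8798 had enough counts to be tested. Across genes, log2 CPM (scaled counts per 1000000) correlated at r = 0.959 between the controls, 0.985 between the knockdown libraries and 0.908 to 0.951 between groups. The first principal component held 70.5% of the variance and separated the groups, and the second held 25.2% and separated the libraries numbered 1 from those numbered 2 in both groups. Eggshell genes took 0.975% and 3.48% of the counts in control 1 and control 2, and 0.154% and 1.03% in knockdown 1 and knockdown 2.

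The transcript of HP1a stood at 253 and 229 CPM in control 1 and control 2 and at 224 and 236 CPM in knockdown 1 and knockdown 2. Its log2 fold change was -0.06 (SE 0.11, adjusted p = 0.677), so that no change was detected in whole-ovary RNA, and the knockdown named by the labels was not seen in this transcript. Whether it fell in the somatic cells cannot be read from these libraries, which are called knockdown after their labels. The value was 0.17 with library size alone as the scale and 0.46 (adjusted p = 0.0123) with limma-trend on TPM, where the median of all genes was 0.25 and 0.50, so that relative to other genes it did not rise under either. Without control 1 it was 0.02.

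Between the groups, 2455 of 8798 genes (27.9%) passed an adjusted p of 0.05, with 1040 higher and 1415 lower in the knockdown libraries. Falls were the larger changes: 745 genes were lower by at least 2-fold and 312 higher, and at 8-fold the counts were 153 and 39. An unadjusted p under 0.05 was reached by 4236 genes, against 440 by chance, and the smallest adjusted p was 0.0217. Values of the groups did not overlap for 6778 tested genes (77.0%, against 33.3% by chance). The number of calls changed widely with the library left out. In such a fit 1 group has a single library, and the spread comes from the other group. The controls were less alike (r = 0.959) than the knockdown libraries (r = 0.985). Counts of calls with a library left out, here and below, therefore cannot show that an effect rests on that library. The split by direction changed with the scale: genes higher made up 42.4% of calls as scaled here, 71.2% with library size alone and 18.8% when scaled to a germline gene list, with medians of all genes of 0.25 and -0.25. With limma-trend on TPM, which changes the test and the treatment of length beside the scale, the share was 86.9% and the median of all genes 0.50.

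**Figure D1:**
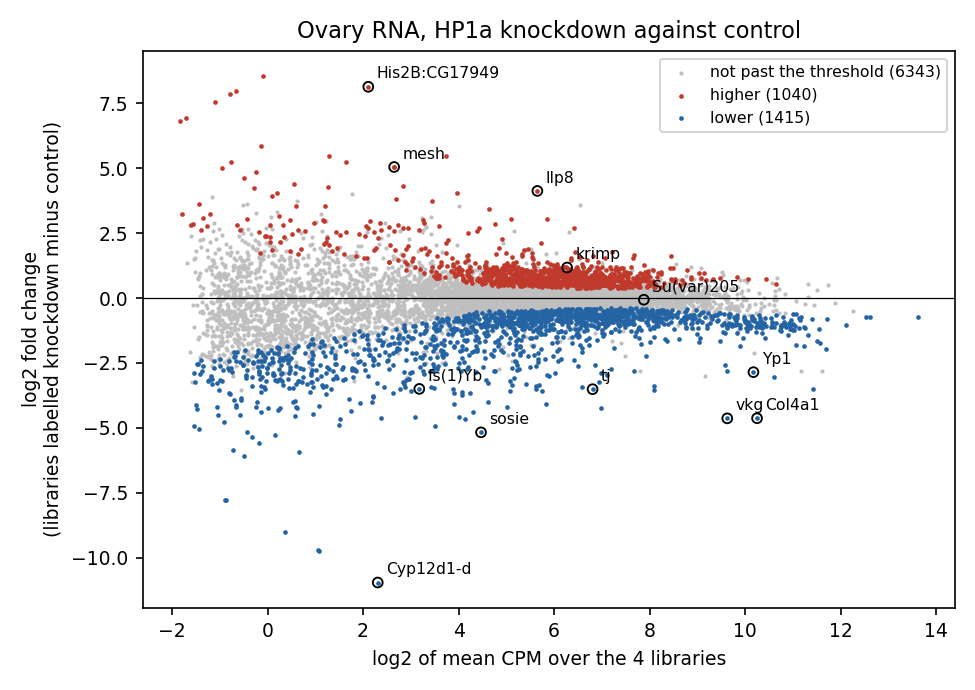
Log2 fold change (knockdown minus control) against mean expression for all tested genes, with the genes past the threshold in colour. The direction split of the coloured genes depends on the scale used.

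Among the 12 largest rises with at least 50 counts on average were mesh (33.1-fold, log2 fold change 5.05, SE 1.16, adjusted p = 0.0367), a transcript of the Stellate family, SteXh:CG42398 (33.5-fold, log2 fold change 5.07, SE 0.35), and the relaxin-like hormone gene Ilp8 (17.5-fold, log2 fold change 4.13, SE 1.01, adjusted p = 0.0409). Ilp8 went from 5.41 CPM (SD 6.53) in the controls to 95.1 CPM (SD 12.7), and mesh from 0.368 CPM (SD 0.521) to 12.2 CPM (SD 5.0). Osi24 rose 44.5-fold and Tsf1 14.1-fold. CG5399, CG14245, Fad2, CG18628 and CG12517 rose by log2 fold changes of 3.75 to 5.25. In control 1 and control 2, Osi24 had 2 and 2 counts, CG5399 had 3 and 3, and Fad2 had 4 and 5. The size of their rises is therefore uncertain. The remaining pair were histone copies, His2B:CG33890 (44.6-fold) and His2B:CG17949. The latter had 1 count in the controls and 477 in the knockdown libraries, a ratio of 304 with a 95% counting interval of 54.3 to 12039. Near-identical copies share reads, so the value of a single copy is uncertain. All of the 12 but SteXh:CG42398 stood higher in knockdown 1 than in knockdown 2. The gap was wide for Fad2 (8.08 and 1.06 CPM), Tsf1 (19.0 and 4.98 CPM) and CG5399 (9.15 and 2.97 CPM). Without knockdown 1, 8 of the 12 (mesh, Ilp8, Tsf1, Fad2, CG5399, CG14245, CG12517 and His2B:CG33890) no longer passed, and Fad2 and Tsf1 did not pass without control 1 or control 2 either.

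All 12 of the largest falls passed without each library in turn. The collagen IV genes vkg and Col4a1 fell 24.9-fold and 24.8-fold, vkg from 1520 CPM (SD 868) to 61.1 CPM (SD 22.7) and Col4a1 from 2342 CPM (SD 1302) to 94.5 CPM (SD 31.0). The gene sosie fell 36.1-fold (log2 fold change -5.17, SE 0.24, adjusted p = 0.0217), from 43.2 CPM (SD 6.68) to 1.17 CPM (SD 0.218). Wnt4 (24.8-fold), klu (23.8-fold), GstE14 (23.7-fold) and CadN (21.2-fold) fell as well, and so did CG15529, CG16820, CG6044 and CG42566, by log2 fold changes of -4.65 to -4.94. Cyp12d1-d had 219 and 167 counts in the controls and 0 in both knockdown libraries, at least 202-fold lower with a floor of 3 counts over the group. Its neighbouring copy Cyp12d1-p fell less (log2 fold change -1.27, SE 0.22, adjusted p = 0.0255), and the sum of both copies fell 4.13-fold. As for the histone copies, reads can be shared between them, so the value of the single copy is uncertain. Whether the lines differ at these copies was not tested.

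**Figure D2:**
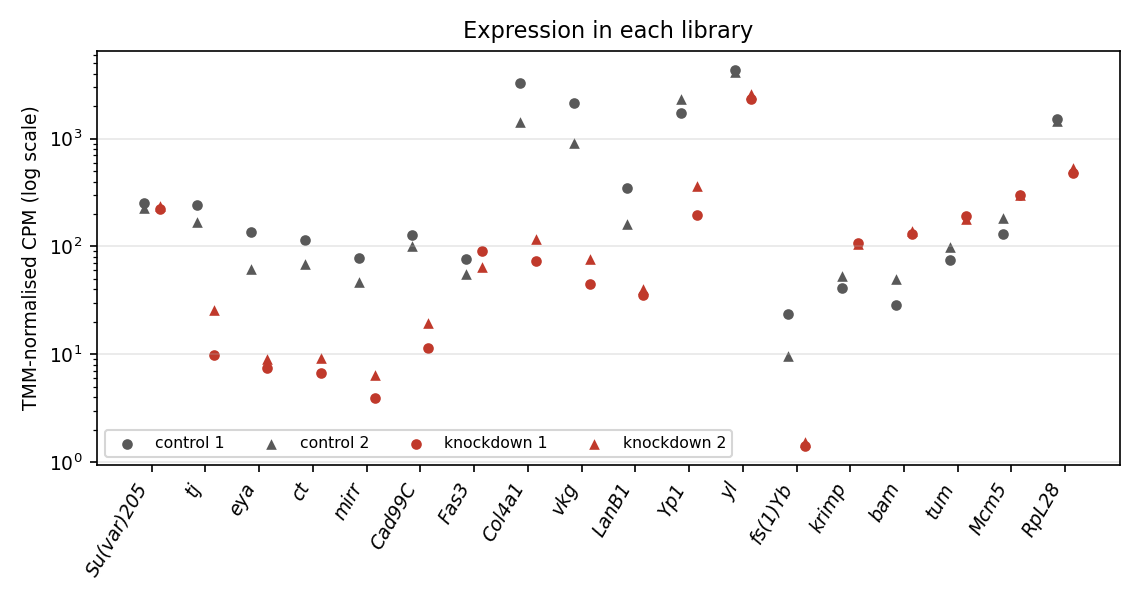
CPM in each library for the knockdown target and for selected genes of the lists, which fell (such as tj and vkg), rose (such as bam) or did not pass (Fas3). Points are single libraries.

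Transcripts of follicle cells, the main somatic cells of the ovary, were lower. Of 21 tested follicle cell genes, 12 fell and 0 rose (13 and 0 adjusted over the list alone), with a median log2 fold change of -2.46 (adjusted p = 7.00e-07 for the list). That call was not made with an estimated correlation between genes (adjusted p = 0.700), under which no list passed. Of the 21 genes, 6 also belong to the eggshell list, in which the controls differed strongly. The 15 outside that list had a median of -2.75, and 11 of them were called lower. The gene tj fell 11.4-fold (log2 fold change -3.51, SE 0.50, adjusted p = 0.0221), from 206 CPM (SD 53.4) to 17.9 CPM (SD 11.3). The regulators eya (log2 fold change -3.59), cas (15.9-fold), mirr (11.8-fold) and ct (11.4-fold) fell by similar amounts, Cad99C by 7.36-fold and peb by 3.78-fold, whereas Fas3 (0.23, adjusted p = 0.469), dome (0.22, adjusted p = 0.204) and ttk (-0.31, adjusted p = 0.184) did not pass. The list median was -3.31 without knockdown 2, -2.03 without knockdown 1, -2.35 without control 1 and -2.08 without control 2. Without knockdown 1, 8 of the members were lower, and 10 were without knockdown 2 or control 1; without control 2, 10 were lower and 3 higher.

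Eggshell genes did not pass as a list (37 tested, 0 higher and 3 lower, 0 and 1 adjusted over the list alone; median -1.31, adjusted p = 0.0503), and control libraries differed strongly in them: Cp15 stood at 0.631 and 1326 CPM in control 1 and control 2, and at 38.7 and 546 CPM in knockdown 1 and knockdown 2. The list median was -2.28 without control 1 (adjusted p = 5.02e-08), 4.42 without control 2 (adjusted p = 0.518) and -4.39 without knockdown 2 (adjusted p = 1.16e-13). The yolk protein genes Yp1 (7.24-fold), Yp2 (8.17-fold) and Yp3 (6.03-fold) were lower, and their receptor gene yl fell 1.74-fold. Over the 9 yolk and uptake genes 4 were lower and 0 higher (4 and 1 adjusted over the list alone); the median was 0.09, the mean -0.37 and the camera test pointed down without passing (adjusted p = 0.271), while fry called the list (adjusted p = 0.0405).

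The list of hemocyte and basement membrane genes did not pass, and its members went both ways: 2 of 20 were higher and 6 lower (3 and 8 adjusted over the list alone; median -0.46, adjusted p = 0.0989; 0.0388 without control 2 and 0.010 without knockdown 1; median -0.058 and adjusted p = 0.505 without control 1). Beside the collagens, LanA fell 11.7-fold, LanB2 9.35-fold, LanB1 6.73-fold and SPARC 3.92-fold. Pxn rose 3.35-fold (adjusted p = 0.0426) and crq 1.98-fold (adjusted p = 0.0288), and Hml (1.63, adjusted p = 0.0761) and NimC1 (1.28, adjusted p = 0.214) did not pass. With limma-trend on TPM the list median was 0.06, where the median of all genes was 0.50 or more. No part of the list was tested by itself.

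Ecdysone genes were lower as a list (19 tested, 2 higher and 8 lower, 3 and 9 adjusted over the list alone; median -0.98, adjusted p = 0.0140), though neither without control 2 (adjusted p = 0.204) nor with an estimated correlation (adjusted p = 0.700). The steroid synthesis genes sad (5.75-fold), dib (-3.31) and spo (-2.41) fell, as did the coactivator gene tai (3.09-fold), Eip74EF (4.06-fold) and Hr4 (-1.28). EcR (0.50) and the importer gene Oatp74D (1.27) rose.

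Nearly all cytosolic ribosomal protein genes fell: 80 of 83 were lower and 0 higher (81 and 0 adjusted over the list alone), with a median log2 fold change of -1.08 (2.11-fold, adjusted p = 1.51e-25 for the list; adjusted p = 0.700 with an estimated correlation). Together they took 15.7% and 12.8% of the counts in the controls and 7.72% and 7.5% in the knockdown libraries. RpL28 fell 2.94-fold. The median stayed negative under each scale tried, from -1.35 to -0.54. Fewer single members passed without a knockdown library (1 of 83 lower without knockdown 1 and 7 without knockdown 2), while the median stayed at -1.06 and -1.07 (adjusted p = 1.80e-18 and 7.69e-19 for the list). Transcripts of the mitochondrial genome did not pass as a list (13 tested, 0 higher and 3 lower, 0 and 3 adjusted over the list alone, median -0.37, adjusted p = 0.163). Their median was 0.14 with limma-trend on TPM, below the median of all genes there (0.50).

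Mitosis genes were higher, 13 of 37 with 0 lower (30 and 0 adjusted over the list alone; median 0.72, adjusted p = 1.85e-08; adjusted p = 0.700 with an estimated correlation). DNA replication genes were higher too, 7 of 36 with 0 lower (15 and 0 adjusted over the list alone; median 0.58, adjusted p = 2.12e-05; adjusted p = 0.700 with an estimated correlation). Among them were sub (2.28-fold), fzy (2.17-fold), tum (2.14-fold) and Mcm5 (1.91-fold). None of these members passed without knockdown 1 or without knockdown 2, whereas 35 mitosis and 31 replication genes were higher without control 2. Both medians stayed positive under every scale; without control 1 they were 0.47 (mitosis) and 0.35 (replication), and without control 2 they were 1.09 and 0.89.

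Germline genes did not pass as a list (41 tested, 7 higher and 2 lower, 3 and 2 adjusted over the list alone; median 0.24, adjusted p = 0.0503), though they did without control 2 (adjusted p = 0.0260) and without knockdown 1 (adjusted p = 0.0267). The differentiation gene bam rose 3.42-fold (log2 fold change 1.77, SE 0.28, adjusted p = 0.0239), and grk fell 1.93-fold. In the piRNA pathway, 5 of 32 genes were higher and 3 lower (5 and 3 adjusted over the list alone; median 0.07, mean -0.04, list test upward with adjusted p = 0.482). Among the 3 lower genes was fs(1)Yb, of the somatic branch of the pathway, which fell 11.3-fold (log2 fold change -3.50, SE 0.52, adjusted p = 0.0232). Among the 5 higher were krimp (2.26-fold), Gasz (1.79-fold) and AGO3 (1.77-fold). Other lower members are not named here, so these genes do not show how branches of the pathway moved. piwi (-0.52, adjusted p = 0.0657) and armi (-0.84, adjusted p = 0.0712) did not pass.

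**Figure D3:**
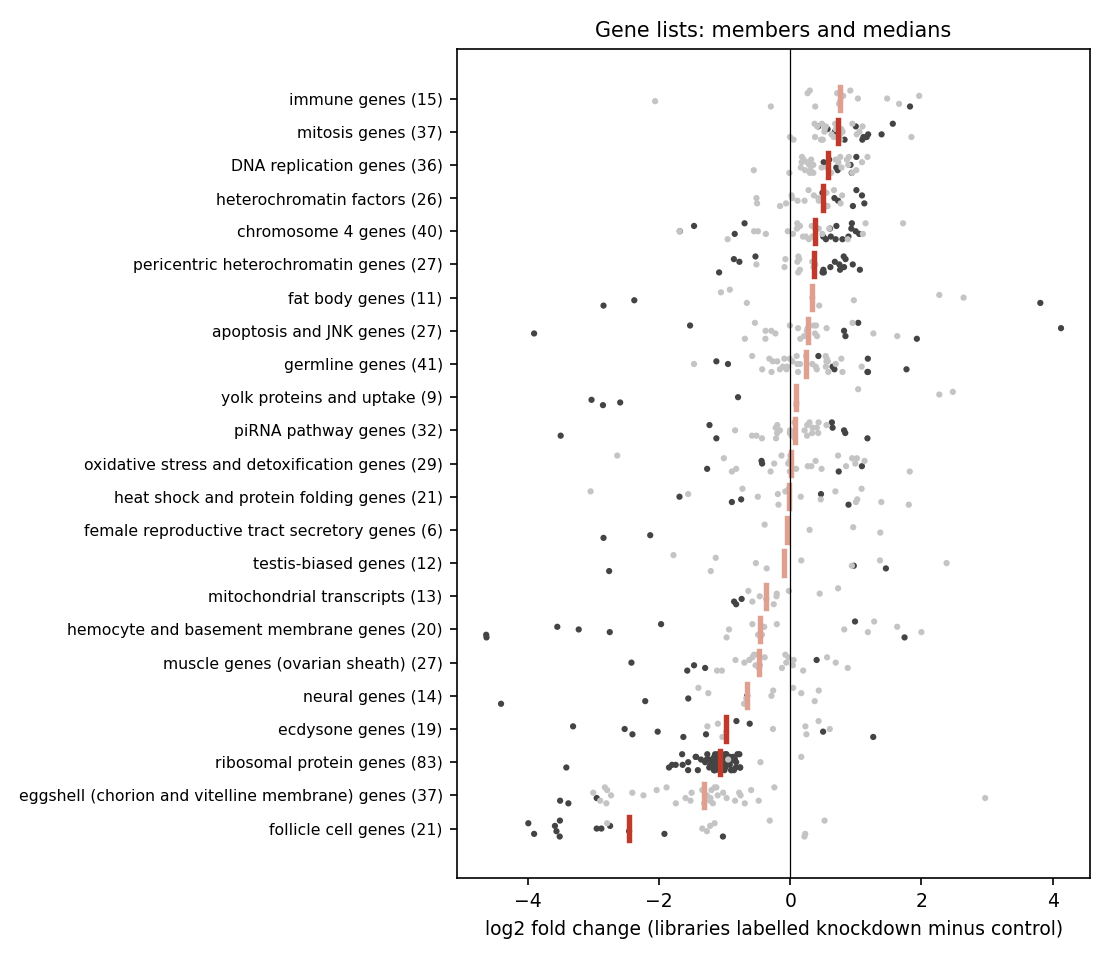
Log2 fold change of the tested members of each gene list, with list medians. The lists overlap by up to 7 genes.

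Genes in or near heterochromatin were tested next. Of 40 genes listed for chromosome 4, 12 rose and 4 fell (15 and 5 adjusted over the list alone; median 0.38, adjusted p = 0.0165), and of 27 pericentric genes 12 rose and 4 fell (12 and 4 adjusted over the list alone; median 0.35, adjusted p = 0.0446). Neither call was made with an estimated correlation (adjusted p = 0.700 for both). The first was not made without control 2 (median 0.52, adjusted p = 0.0525) or without knockdown 2 (median 0.47, adjusted p = 0.0698), and was made with germline scaling at a smaller median (0.11, adjusted p = 0.0127); the second was not made without control 1 (median 0.15, adjusted p = 0.0551), without knockdown 2 (adjusted p = 0.0698), with germline scaling (median 0.09, adjusted p = 0.0544) or with the replicate number as a block (adjusted p = 0.0537). Its median was 0.59 without control 2. Fry called the chromosome 4 list (adjusted p = 0.0376) and not the pericentric list (adjusted p = 0.157). On chromosome 4, PMCA (0.80), PlexB (0.89), Ephrin (1.05) and pho (1.00) rose, and ci (-1.68) and bt (-1.47) fell. Among pericentric genes CG17528 (0.76), Nipped-B (0.95) and Haspin (1.06) rose, and RpL15 (-1.08), RpL38 (-0.78) and RpL5 (-0.86) fell. Genes for heterochromatin factors were higher, 8 of 26 with 0 lower (9 and 1 adjusted over the list alone; median 0.51, adjusted p = 0.00559; adjusted p = 0.700 with an estimated correlation), among them E(var)3-9 (1.13), Rif1 (0.73), Su(var)2-10 (0.67) and prod (0.56). No member of these 3 lists passed without knockdown 1 or without knockdown 2.

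Of the tested genes, 8581 were placed on an arm and 217 were not. On chromosome 4, 16 of 68 genes rose and 7 fell (23.5% and 10.3%), with a median of 0.30 (adjusted p = 0.0324 with camera; adjusted p = 0.227 with an estimated correlation). On the other arms 9.38% to 13.6% of genes rose and 14.9% to 17.6% fell, the medians lay between -0.04 and 0.06, and no other arm passed with camera (adjusted p = 0.706 to 0.998). Fry, which does not compare an arm with other genes, called chromosome 4 (adjusted p = 0.00757), 3L (adjusted p = 0.0135) and X (adjusted p = 0.0168). The camera call for chromosome 4 was also not made with the replicate number as a block (adjusted p = 0.0588), without control 2 (adjusted p = 0.187) or without knockdown 2 (adjusted p = 0.103).

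Called genes lay next to each other more often than calls reassigned at random among tested genes. There were 149 adjacent pairs of higher genes, against a mean of 121 in 10000 reassignments (range 87 to 155, one-sided permutation p = 0.002), and 287 pairs of lower genes, against a mean of 219 (range 169 to 266, p = 1e-04, the smallest that these reassignments can give). Genes are not independent replicates, and neighbours can be paralogs. With 1000 reassignments each, without knockdown 1 there were 1 and 7 pairs (permutation p = 0.0759 and 0.103), without knockdown 2 there were 2 and 17 (p = 0.179 and 0.002), and without control 2 there were 771 and 519. The longest run held 8 lower genes on the X chromosome, from Myc to CG10804, and the longest run of higher genes on 2R was Cyp6a22, Cyp6a23, Cyp6a19 and Cyp6a9.

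The other lists did not pass with camera. Members changed in both directions for apoptosis and JNK genes (27 tested, 5 higher and 2 lower, 4 and 1 adjusted over the list alone; median 0.27, adjusted p = 0.121; 0.0263 without knockdown 2), where Mmp2 rose 3.81-fold and Socs36E fell (-1.53). Heat shock genes (21 tested, 2 and 3, 4 and 5 adjusted over the list alone) had a median of -0.02 and a mean of -0.03 with a list test upward (adjusted p = 0.887), and detoxification genes (29 tested, 2 and 3, 2 and 1 adjusted over the list alone) a median of 0.01 (adjusted p = 0.830). Testis-biased genes (12 tested, 2 and 1, 3 and 1 adjusted over the list alone) had a median of -0.10 and a mean of -0.04 with a list test upward (adjusted p = 0.830). Immune genes (15 tested, 1 and 0, 0 and 0 adjusted over the list alone) had a median of 0.76 (adjusted p = 0.0503; 0.0283 without control 1 and 0.0126 without knockdown 2), with Tep2 higher (1.83), and neural genes (14 tested, 0 and 4, 1 and 5 adjusted over the list alone) a median of -0.66 (adjusted p = 0.0503; median -0.23 and adjusted p = 0.143 without control 1), with futsch lower (-2.21). Muscle genes (27 tested, 1 and 4, 0 and 4 adjusted over the list alone) had a median of -0.48 (adjusted p = 0.171; 0.00137 without control 2 and 0.0300 without knockdown 1; median 0.045 and adjusted p = 0.946 without control 1), fat body genes (11 tested, 1 and 2, 3 and 2 adjusted over the list alone) a median of 0.34 (adjusted p = 0.887), and secretory genes of the female tract (6 tested, 0 and 2, 0 and 2 adjusted over the list alone) a median of -0.05 (adjusted p = 0.887; 0.0164 without knockdown 2). The 2 gut genes with enough counts, Try29F (-3.39) and LManI (-2.75), were both lower. Of the female tract genes with too few counts to be tested, CG32834, Send1 and CG17239 had 165, 93 and 23 counts in knockdown 1. They had 0 in each other library. The remaining untested members of that list had at most 19 counts in any library. Why knockdown 1 differed in these genes was not tested.

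The deposited list of HP1 domains in ovaries held 4467 domains in dm3 coordinates, a single list without a score or values per DamID library. They covered 15.3 Mb, 13.3% of the span from the first to the last domain of each arm, with a median length of 2000 bp; 790 (17.7%) were a single bin of 500 bp, and 285 of at least 10 kb held 29.4% of the covered length. The X chromosome carried 48.4 domains per Mb and 15.7% coverage, against 35 to 38.4 per Mb and 12.4% to 13.1% on 2L, 2R, 3L and 3R. Coverage in blocks of 1 Mb had medians of 15.6% on the X and 10.8% to 12.2% on the other arms. The densest blocks were the first Mb of 3R (34.8%), 2R from 2000001 to 3000000 (31.5%) and 2L from 21000001 to 22000000 (27.9%). The longest domains lay on 2L at 21604501 to 21653500 (49000 bp), on 3L at 17251001 to 17295000 (44000 bp) and on X at 15834501 to 15878000 (43500 bp). No domain was listed on chromosome 4, and the list does not say whether that chromosome was searched. Nor does it say whether the ends of the arms were searched. The first domain on 2R began at 1643501, against 1 to 19501 on the other arms, and the last on 2L and 3L ended at 22000500 and 22900500. Coverage and domains per Mb therefore describe the listed spans and not whole arms. Overlap between domains and the genes that changed was not analysed here, for want of gene coordinates in the same build.

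**Figure D4:**
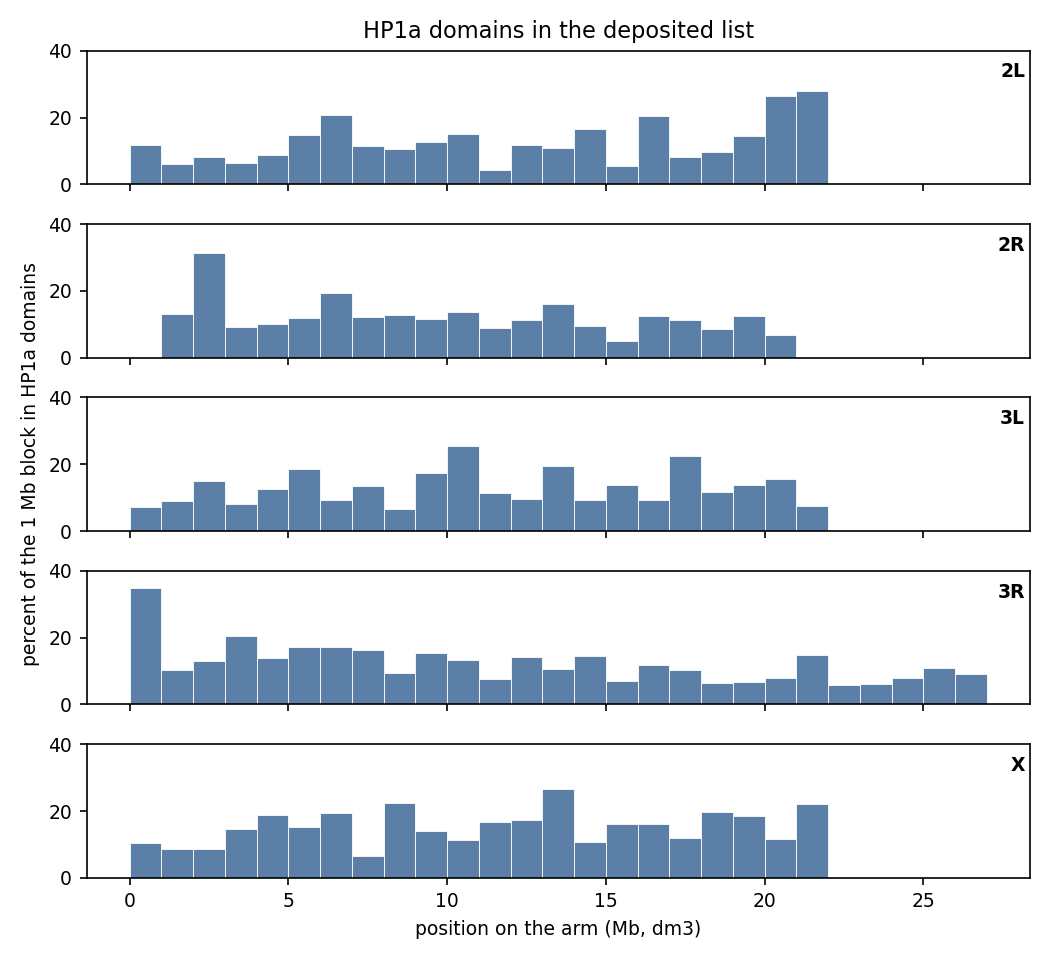
Share of each 1 Mb block covered by the deposited HP1 domains along the 5 chromosome arms. Positions are in dm3 coordinates.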

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

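Scaling to the germline list and the alternatives for chromosome 4 by annotation, neighbours and summed histone copies were chosen after seeing the data. Of 2107 values of the 112 named genes and list examples under an alternative, 1712 kept direction and side of the threshold, 325 kept direction and no longer passed, 62 newly passed and 8 reversed; none of the 24 largest rises and falls reversed. The reversals were the HP1a gene (library size alone 0.17; TPM + 1 and TPM + 0.1 both 0.46; -0.093 to 0.016 over the libraries left out), Sod2 (0.11 on both TPM scales) and mt:CoI (0.066 on both). On the TPM scales the median of all genes was 0.50 and 0.56, so that relative to other genes none of them rose there. Genes past the threshold numbered 5070 (4406 higher, 664 lower) with TPM + 1, 5046 (4377 and 669) with TPM + 0.1, 3713 (1834 higher) with the replicate block and 1057 (312 and 745) at a log2 fold change of at least 1. Genes higher numbered 2576 with library size alone and 1688 with DESeq2, and 517 were higher and 2232 lower with germline scaling; library size alone and germline scaling move all genes together, whereas limma-trend on TPM changes test, length treatment and scale at once, and for it and the rest the cause was not tested. At an adjusted p of 0.01, edgeR called 0 genes (0 higher, 0 lower), with 4236 at an unadjusted p under 0.05; at 0.05 DESeq2 called 3318 and limma-voom 2711. Leaving out a library gave 220 to 4543 calls (29 to 2540 higher, 191 to 2003 lower), the lowest without knockdown 1, of whose 220 calls 214 were among the 2455; the lone library of a group is then assumed to vary like the other group. Samples of the groups share only a number, yet the differences between numbers 1 and 2 correlated across genes (r = 0.50, and 0.37 without eggshell genes).

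Lists past the threshold numbered 14 with DESeq2, 13 with the block, 5 at an adjusted p of 0.01, 0 with an estimated correlation and 2 with fry, where ribosomal protein genes (-1.08) had adjusted p = 0.700 and 0.137; the cause was not tested. With the block, eggshell genes (adjusted p = 5.61e-06), yolk and uptake genes (0.0166) and germline, hemocyte and basement membrane, immune and neural genes (0.0422 each) passed, and pericentric genes did not (0.0537). Pericentric genes kept direction without passing in 10 of 20 alternatives. Chromosome 4 by annotation no longer passed with the block (0.30, adjusted p = 0.0588) or an estimated correlation (0.30, adjusted p = 0.227), and was 0.31 to 0.33 over the libraries left out. Neighbouring pairs ranged from 1 to 771 (higher) and 7 to 519 (lower) over the libraries left out. Directions of list tests that reversed, given as medians, all belonged to lists not past the threshold (the sign of the median can differ from the test): testis-biased genes (library size alone 0.14; TPM 0.20 and 0.46; no filter -0.053; at least 10 counts -0.77; -0.48 to 0.58 over the libraries left out), heat shock genes (library size alone 0.22; DESeq2 0.0025; limma-voom -0.043; TPM 0.45 and 0.49; length offset 0.14; fry -0.023; -0.53 to 0.37), fat body genes (library size alone 0.58; limma-voom 0.30; TPM 0.84 and 0.86; no filter 0.38; at least 10 counts -0.18; -0.018 to 0.38) and secretory genes of the female tract (limma-voom 0.079; no filter -0.011; germline scaling -0.29; -0.39 to 0.54). Only over the libraries left out did detoxification genes (-0.025 to 0.28), muscle genes (-0.78 to 0.045) and eggshell genes (-4.39 to 4.42) reverse; the cause was not tested. Of the summed histone families, His3 no longer passed without knockdown 1 (1.13) or knockdown 2 (1.35), and His2A passed with library size alone (1.52), without control 1 (0.79) and without control 2 (2.10). Domains numbered 3677 (13% of the span) with a minimum of 1000 bp and 3934 (13.5%) when merged. Domains by score were not run, as the list has no score, nor were the alternatives for overlap with genes, as no gene coordinates in dm3 were at hand. The 4978 genes not tested had too few counts; whether for depth or for lack of expression was not tested.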

Other observations

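The groups of genes outside the fixed lists, the white gene, the summed histone families and all 9 tests in this part were chosen after the result was seen. So were the bounds the tests were held to. The follicle cell and ribosomal protein lists were fixed beforehand, and so were the other scales except germline scaling.

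Some groups of genes outside the fixed lists, defined by their symbols, held mostly lower members; no enrichment was tested for them. All 71 tested mitochondrial ribosomal protein genes had negative log2 fold changes (median -0.58) and 42 passed, and of 34 complex I subunit genes 26 passed, all lower (median -0.68). Translation initiation factor genes (19 of 36 lower, median -0.56) and tRNA synthetase genes (9 of 19 lower, median -0.47) had calls in the same direction. Of 35 proteasome genes 1 was higher and 1 lower (median -0.07), and of 14 V-ATPase genes 0 passed with edgeR (median 0.14); differences between groups were not tested. With log2(TPM + 1) the medians of the first 4 groups were -0.04, -0.15, -0.02 and 0.06, so that the sign for tRNA synthetase genes flipped, while the median of all genes was 0.50. In all, 15 groups defined by the start or end of the symbol, or by a short set of names, were looked at. Of 51 cytochrome P450 genes, 8 were higher and 4 lower. The transcript of the white gene, which transgenes often carry as a marker, was 10.6-fold lower (497 CPM in the controls, 47.0 CPM in the knockdown libraries, adjusted p = 0.0219).

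The fall of follicle cell genes was weighed against 3 explanations. Under 7 other scales, of which the 2 on TPM also changed the test, the highest list median was -1.28, which argues against the choice of scaling as the whole cause. A mix of late egg chambers that varies as it does between the controls was tested on the 15 members outside the eggshell list: for 10 the lowest control value was at least 2-fold the highest knockdown value, which just meets the bound of 2 in 3 written after the value was known, so that the count by itself argues weakly. Between the controls the same members differed by a median of 0.47 on the log2 scale, against 6.49 for eggshell genes. Between groups their median log2 fold change was -2.75. These values argue against a mix that varies as it did in this single pair of controls. Other shifts in the stage of egg chambers were not tested. A lower share of follicle cells in the knockdown ovaries stays open. Over the 15 members the log2 fold changes ran from -3.99 to 0.52 (SD 1.65), and 4 did not pass, among them Fas3 (0.23), dome (0.22) and ttk (-0.31). An equal loss of all follicle cells by itself would not give this spread, but subtypes could be lost unequally, other cells could express some of the members, and whole-ovary RNA cannot separate fewer cells from less transcript per cell.

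For the fall of ribosomal protein genes, the highest median under 7 other scales was -0.54, so that scaling alone does not account for it. In 10000 random lists of other genes matched on length and expression (within 1 log2 unit), the lowest median was -0.70 and the middle one -0.28, against -1.08; matched genes were somewhat longer (430 against 356 nt at the median) and 1 gene had a single match, but short and abundant transcripts as a class fell less. A lower share of somatic cells may contribute and cannot be told apart from a lower level per cell: between the controls the genes differed by a median log2 ratio of 0.29, in the direction of the follicle cell genes (0.34), and 2 controls are too few to relate them.

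Histone transcripts were higher in this poly(A)+ RNA. Reads divided between near-identical copies were addressed by summing the copies of each family: the lowest of the 5 log2 fold changes was 1.23, and His1 (7.06-fold), His4 (6.31-fold), His2B (4.6-fold) and His3 (2.34-fold) passed while His2A (1.29, adjusted p = 0.0685) did not, so that division between copies does not account for the rise. Under 4 other scales the lowest value was 0.98, which argues against the scale. The log2 fold changes of His1 and His4 were both 2.16 without control 1, and 4.12 and 3.48 without control 2. His3 did not pass without knockdown 1 (adjusted p = 0.128) or without knockdown 2 (adjusted p = 0.0788). A larger share of cells in DNA replication may add to it, as replication genes had a median of 0.58, below that of each histone family; more histone RNA with a poly(A) tail was not tested, and the values cannot decide between them.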
